A study of Rattus norvegicus with 36 samples.

How the data were processed

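The series holds small RNA libraries from 3 tissues (PFC, NAc and serum) of rats that self-administered heroin or saline, with 6 libraries in each of 6 groups. Per the labels' protocols, the male Sprague Dawley rats arrived at 8 weeks of age, had 1 week to acclimatise, received a jugular catheter and recovered for 1 week before the sessions began. RNA came from brain tissue by Trizol and from trunk blood serum with a kit for exosomal RNA, and inserts of 18 to 40 bp were sequenced. The labels number heroin libraries 1 to 6 and saline libraries 7 to 12 in each tissue and call them biological replicates. They do not say that a number marks the same animal in different tissues. Every library was placed in its group from its label.

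Read counts per mature miRNA were used as deposited, with 1 column for each library, and no replicates were pooled. TPM values per miRNA were deposited beside the counts, per the file headers. All 30996 TPM values equalled the count divided by the library's total of the table and multiplied by 1e+06, to within a relative difference of 4.9e-15, so TPM here has no length term. Bowtie and the rat genome build rn6 are named per the submitters' processing notes. The role and version of Bowtie, the miRNA annotation release, the rule for reads that match several miRNAs and the tool that predicted 155 of the 861 names are not given in the sources used here. The predicted names took at most 0.134% of the counts of a library. All 72 columns of counts and TPM matched the label of a library.

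Names whose counts nearly repeat each other were searched for: 31 pairs had at least 500 summed counts each and differed by at most 5%, 25 of them by under 1%. The measure was the absolute difference summed over libraries, as a share of the counts of both names together. No sequence was used here to tell the names apart. Both names of a pair stayed in the fits and lists, and an added alternative counted each pair once. Replicates were compared for identity: over 90 pairs within groups, the smallest chi-square per degree of freedom was 56.7, so no pair agreed within sampling noise. That cannot show that libraries come from separate animals. Every library counts as 1 replicate on the word of the labels. No date, lane or batch is given in the labels. Total counts bound the precision: in the shallowest serum library of 157415 counts, 1 count stands for more than 6 CPM, against well under 1 CPM in any brain library.

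Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr with a minimum count of 10 and Benjamini-Hochberg adjustment at 0.05. Each comparison was fitted on its own groups, with no replicate block. The comparisons were heroin against saline within each tissue, the difference of that effect between each pair of tissues as an interaction, and each pair of tissues in saline rats. Log2 fold changes of edgeR carry a standard error derived from the test, the size of the log2 fold change divided by the square root of F. CPM values are counts scaled to a library total of 1e+06, given as mean ± SD. "Passed" and "called" mean an adjusted p under 0.05. Beside counts of miRNAs whose 6 against 6 libraries do not overlap, chance gives 0.216%.

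The comparisons, tests, named miRNAs, alternatives and 20 lists were chosen before the data were examined, except where an alternative is said to have been added. The lists hold 197 miRNAs, of which 3 are not in the table, and are called neuron-enriched, activity and synaptic plasticity, opioid- or reward-linked in earlier work, let-7, oligodendrocyte, astrocyte, leukocyte and microglia, erythrocyte, platelet, liver, striated muscle, vascular, choroid plexus and ciliated ependyma, miR-200 family, Hox-cluster, Dlk1-Dio3 cluster, miR-17 cluster with its paralogs, miR-29, miR-30, and inflammation. They share members, and many mark more than 1 cell type. Lists with at least 3 measured members were tested with camera of limma 3.58.1 on log-CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. The same lists were also tested with an estimated correlation and with fry.

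The named miRNAs follow a rule. For each heroin comparison it takes up to 10 miRNAs in each direction past the threshold, filled to 10 with the smallest p-values where fewer pass, a fixed panel of neuronal, blood, liver and vascular miRNAs, and at most 4 measured members of each list with the smallest p. For an interaction with no call it takes the 3 with the smallest p. For tissue comparisons it takes the 10 largest log2 fold changes in each direction with a mean of at least 100 CPM in the higher tissue, and for abundance the 10 leading names. List members given as examples in the tissue comparisons were chosen after their values were seen. Members with 1 to 3 counts in a group are given as levels.

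Correlations of heroin effects between tissues were tested with 100 relabellings of the libraries within each tissue. The red cell ratio was tested over all 924 assignments of the 12 serum libraries, two-sided.

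The alternatives were RLE size factors, upper-quartile factors, library size alone, DESeq2 1.42.0, limma-voom with quality weights, limma on log2(TPM + 1), no filter and a filter of at least 10 CPM in 6 libraries. Others were the 5 most abundant miRNAs left out, robust dispersion, the red cell ratio as a covariate, the erythrocyte list left out, a replicate block, all 36 libraries in one fit, and each library left out in turn. Added after the data were seen were pairs of repeated names counted once, PFC saline replicates 8 and 12 and serum saline replicate 12 left out, the 4 brain libraries highest in miR-122-5p left out, and serum saline replicates 10, 11 and 12 left out.

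The edgeR fits were tested on simulated counts with 200 miRNAs changed by known folds in each comparison. So many changes make the adjusted threshold easier to pass than a few changes would. For heroin against saline, changes of 1.5-fold, 2-fold and 4-fold were recovered for 8.1%, 43.3% and 94.9% of miRNAs in the PFC (455 simulated), 27.5%, 72.5% and 96.8% in the NAc (480) and 16.9%, 43.1% and 97.4% in serum (229). For the interactions they were recovered for 12.7%, 18.9% and 81.0% between NAc and PFC (506), 0%, 6.6% and 23.1% between serum and PFC (462) and 2.9%, 4.4% and 31.2% between serum and NAc (489). For the tissues of saline rats they were recovered for 29.0%, 47.6% and 97.1% for NAc against PFC (467), 2.8%, 15.4% and 70.3% for serum against PFC (407) and 13.6%, 40.3% and 94.4% for serum against NAc (424). At most 3.4% of unchanged miRNAs were called in any of them. For lists, 2 of 2 moved lists and 0 of 14, 14 and 13 untouched lists were called in the PFC, NAc and serum, in counts simulated with no correlation between miRNAs.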

Results

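Small RNA was sequenced from the prefrontal cortex (PFC), the nucleus accumbens (NAc, part of the ventral striatum) and the blood serum of adult male Sprague Dawley rats. The rats had access to intravenous heroin at 0.075 mg/kg per infusion, or to saline, for 6 hours a day over 10 sessions, and were killed within 60 min of the last session. Each of the 6 combinations of tissue and treatment had 6 libraries from separate biological replicates, 36 in all. The brain libraries came from total RNA and the serum libraries from an exosome RNA kit. A table of 861 miRNA names, 706 of them annotated rat miRNAs and 155 predicted, held the read counts. The PFC libraries had 3.42 to 20.8 M counts (M, 1e+06; median 10.42), the NAc libraries 5.895 to 24.8 M (median 12.31) and the serum libraries 0.157 to 2.78 M (median 0.456). In serum, 1 count therefore stood for a larger share of the library than in brain, and 313 to 484 names were detected there against 593 to 687 in the PFC and 615 to 691 in the NAc. Heroin and saline libraries did not differ in total counts beyond the spread between replicates in an exact permutation test (two-sided p = 0.872 in the PFC, 0.81 in the NAc and 0.933 in serum, n = 6 per group).

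**Figure D1:**
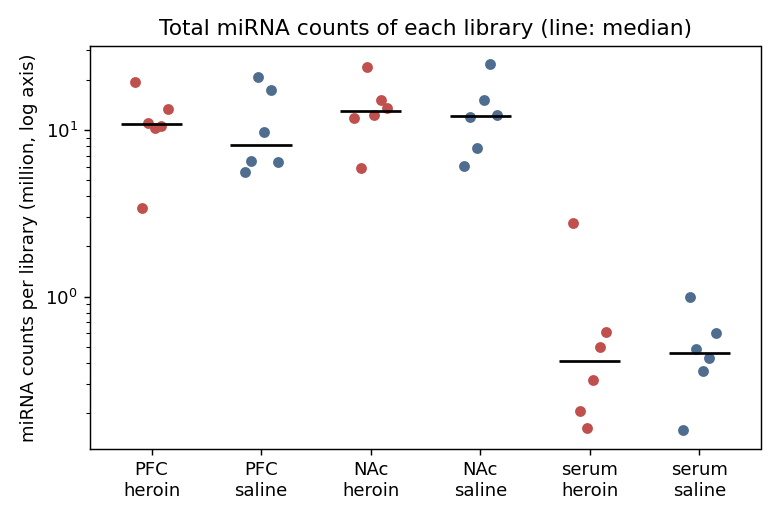
Total miRNA counts of each library in M (1e+06 counts) on a log axis, for heroin (red) and saline (blue) libraries of the PFC, NAc and serum, 6 per group; the black line is the median of the group. Brain libraries lie between 3.42 and 24.8 M and serum libraries between 0.157 and 2.78 M.

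The brain libraries were led by miR-9a-5p, a miRNA of neural progenitors and neurons, which took 15.97% ± 3.45 of the counts in the PFC (SD, n = 12) and 14.7% ± 2.07 in the NAc. In the PFC, the neuronal miR-128-3p followed with 7.75% ± 5.33, and in the NAc miR-7a-5p with 8.51% ± 3.27. The let-7 family member let-7f-5p took 4.92% ± 1.67 in the PFC and 5.3% ± 0.725 in the NAc, and miR-127-3p, from the imprinted Dlk1-Dio3 region, 4.61% ± 0.963 and 4.36% ± 0.855. Serum was led by miR-148a-3p with 20.4% ± 7.85 and let-7i-5p with 10.6% ± 3.87. Serum also held the muscle miRNA miR-1-3p at 3.46% ± 1.76 and the red cell miRNAs miR-451-5p at 2.88% ± 1.58 and miR-486 at 2.87% ± 0.814. The 10 leading names of a tissue took 67.3% of the counts in the PFC, 67.8% in the NAc and 60.9% in serum. Some names, also among these leading 10, nearly repeated each other's counts, so these shares hold the same signal under both names. In the PFC, miR-9b-3p took 15.92% beside miR-9a-5p. In 31 pairs of names, such as miR-9a-5p with miR-9b-3p, let-7f-5p with miR-3596d and miR-1-3p with miR-3571, the difference summed over libraries was at most 5% of the counts of both names together. The second names of the pairs took 13.3% to 26.5% of the counts in PFC libraries, 19.0% to 24.7% in NAc libraries and 6.55% to 13.3% in serum libraries. Both names of a pair stayed in the fits, so numbers of miRNAs and of list members below can hold the same signal under both names.

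The first question of the design was what heroin self-administration does to miRNAs in each tissue. In the PFC, miR-10a-5p, encoded in a Hox gene cluster, had the smallest p-value. Its level was 123.8 ± 99.1 CPM (mean ± SD, n = 6) after heroin and 35.95 ± 22.4 after saline, where CPM is the count scaled to a library total of 1e+06. The log2 fold change was 1.80 ± 0.53 (SE) in edgeR, and 6 of 6 heroin libraries lay above the saline median. Its relative miR-10b-5p stood at 31.6 ± 31.1 against 11.5 ± 8.39 CPM (1.55 ± 0.63). miR-448-3p, encoded in the serotonin receptor gene Htr2c, stood at 13.1 ± 9.47 against 6.4 ± 2.47 CPM (1.17 ± 0.51). On the other side, miR-485-3p was at 142.9 ± 25.5 against 573.6 ± 1093 CPM (-1.86 ± 0.78) and miR-29c-3p at 23.04 ± 10.3 against 77.4 ± 129.5 CPM (-1.39 ± 0.61). Each of these last values came from 1 saline library: without saline replicate 12 that of miR-485-3p was 0.25, and without saline replicate 8 that of miR-29c-3p was -0.06. None of these passed: 0 of 455 miRNAs did so after Benjamini-Hochberg adjustment in edgeR's quasi-likelihood test, the smallest adjusted p being 0.995, and 16 had an unadjusted p under 0.05, where chance alone would give 22.8. DESeq2, limma-voom and limma on the deposited TPM also called 0, with 16, 7 and 2 at an unadjusted p under 0.05.

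The neuronal panel fixed in advance lay close to 0 in the PFC. The log2 fold changes of heroin over saline were -0.40 ± 0.35 for miR-124-3p, 0.13 ± 0.25 for miR-9a-5p, -0.43 ± 0.38 for miR-128-3p and 0.23 ± 0.31 for miR-218a-5p. For miR-132-3p and miR-212-3p, a pair induced by neuronal activity, they were 0.10 ± 0.26 and -0.14 ± 0.33, and for the endothelial miR-126a-3p 0.03 ± 0.23. The blood cell miRNAs miR-451-5p and miR-486 stood at -0.60 ± 0.35 and -0.99 ± 0.51. Without saline replicate 12, miR-486 was at -0.13 and miR-128-3p at 0.11, and without saline replicate 8, miR-124-3p was at -0.03. The liver miRNA miR-122-5p had a log2 fold change of 2.52 ± 1.07 that came from heroin replicate 2 (86.9 CPM); without that library it was 0.05, while that of miR-10a-5p was 1.48. Saline replicates 8 and 12 stood apart from the other PFC libraries (mean correlation with them 0.828 and 0.85): miR-485-3p was at 2804 CPM in replicate 12 and miR-29c-3p at 341.2 CPM in replicate 8. Without both, 0 miRNAs passed in edgeR, and the value of miR-10a-5p was 1.54.

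In saline rats, miR-10a-5p and miR-448-3p were among 17 miRNAs higher in the NAc than in the PFC, a set looked at in the heroin comparison only after its values were seen. Of the 13 of them tested for heroin in the PFC, 12 had positive values, with a median of 0.63, and without heroin replicate 5 the median was 0.13 and 10 were positive. That library held 2019 CPM of miR-1298 and 78360 CPM of miR-7a-5p, against at most 481.4 and 23880 in the other PFC libraries and means of 1550 and 84060 in the NAc of saline rats. The log2 fold changes were 1.54 ± 0.74 for miR-1298 and 1.00 ± 0.57 for miR-7a-5p, and 0.23 and 0.13 without that library. Without it, miR-10a-5p was at 1.73 and miR-448-3p at 0.60. The PFC saline libraries enter both comparisons, so the values are not independent.

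No member of any of the 20 fixed miRNA lists passed in the PFC, and none of the 19 lists that could be tested did so with camera (4 at an unadjusted p under 0.05, 0 with an estimated correlation, 0 with fry). The miR-29 family had 6 of 6 members with negative values, a median of -0.64 and an adjusted p of 0.135, including miR-29b-3p (-0.49 ± 0.28) and miR-29a-3p (-0.29 ± 0.26). Without saline replicate 8 its median was -0.05 and 4 of 6 members were negative, with miR-29c-5p at 0.19 against -0.78 with all libraries. The oligodendrocyte list holds the repeated names miR-219a-2-3p and miR-219b. It also had 6 of 6 negative, with a median of -0.24 (adjusted p = 0.147), including the myelination miRNAs miR-219a-5p (-0.92 ± 0.51) and miR-338-3p (-0.54 ± 0.40). Without saline replicate 12, which held 167.9 CPM of miR-338-3p against 33.65 to 53.77 in the other saline libraries, these were at -0.21 and 0.01, the median was -0.04 and 3 of 6 members were negative. The platelet list had a median of 0.32 (adjusted p = 0.135), with miR-199a-5p at 0.95 ± 0.45 and miR-22-3p at -0.69 ± 0.35, and the liver list 0.22 (adjusted p = 0.147). The adjusted p of the other lists lay between 0.324 and 0.979. Adjusted over the list alone, 1 miRNA passed, miR-10a-5p in the vascular list; the Hox-cluster list, with 2 measured members, was not tested. Median, mean and test differed in sign for the opioid- or reward-linked, let-7, leukocyte, erythrocyte, striated muscle, Dlk1-Dio3 cluster, miR-17 cluster, miR-30 and inflammation lists. Without heroin replicate 5, 4 lists passed (miR-29 and oligodendrocyte down, platelet and vascular up), and without saline replicate 12, 1 did (miR-29, down).

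In the NAc, let-7i-5p stood at 44060 ± 5281 CPM after heroin and 35010 ± 3756 after saline, a log2 fold change of 0.48 ± 0.16 (SE, n = 6 per group). miR-107-3p, of the miR-103 family, stood at 88.0 ± 33.6 against 147.6 ± 37.9 CPM (-0.60 ± 0.23), with 6 of 6 heroin libraries below the saline median. The neuronal miR-129-5p had a log2 fold change of 0.58 ± 0.22, miR-708-3p of 0.95 ± 0.35 and the abundant miR-148a-3p of 0.94 ± 0.37 (64560 ± 29360 against 37390 ± 13190 CPM). Among miRNAs of low count, miR-337-3p was at 0.803 ± 0.388 against 2.16 ± 1.08 CPM (-1.22 ± 0.37). None of these passed: edgeR called 0 of 480 miRNAs (smallest adjusted p 0.686), with 30 at an unadjusted p under 0.05 against 24 by chance, and DESeq2, limma-voom and limma on TPM called 0, with 33, 84 and 35. In the panel, the values were -0.27 ± 0.23 for miR-124-3p, -0.01 ± 0.10 for miR-9a-5p, 0.40 ± 0.27 for miR-128-3p, -0.32 ± 0.24 for miR-132-3p, -0.48 ± 0.32 for miR-212-3p and 0.06 ± 0.20 for miR-146a-5p, a miRNA induced by inflammatory signalling. For let-7a-5p and let-7c-5p they were 0.05 ± 0.21 and 0.15 ± 0.15.

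In the NAc, none of 19 lists passed in camera (2 at an unadjusted p under 0.05, 0 with an estimated correlation, 0 with fry), no member passed, and none did so adjusted over the list alone. In the list of miRNAs linked to opioids or reward in earlier work, 16 of 21 members had negative values (median -0.32, adjusted p = 0.187), among them miR-23b-3p (-0.52 ± 0.27), which has been linked to the mu opioid receptor, and miR-365-3p (-0.62 ± 0.33). In the let-7 family, 8 of 9 were positive (median 0.07, adjusted p = 0.187), and the median was -0.07 with scaling by library size alone and -0.05 without heroin replicate 3. The other lists had an adjusted p of 0.591 or more; the Hox-cluster list again had 2 measured members. Median, mean and test differed in sign for the oligodendrocyte, miR-200, miR-30 and inflammation lists, and the mean of the erythrocyte list was 0. Without heroin replicate 2, 3 lists passed (opioid- or reward-linked and astrocyte down, let-7 up), and without saline replicate 8 or 11, 1 did (let-7, up).

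In serum, the smallest p-values belonged to a neuronal miRNA and to a pair of miRNAs of ciliated cells, and no single miRNA passed. miR-9a-5p stood at 96.8 ± 26.8 CPM after heroin and 873.4 ± 1215 after saline (log2 fold change -3.20 ± 0.85 SE, n = 6 per group), with 6 of 6 heroin libraries below the saline median. Saline replicates 10, 11 and 12 held 1068, 3195 and 765.7 CPM and the other serum libraries 38.1 to 146.4. miR-449a-5p and miR-34c-3p, related miRNAs of multiciliated epithelia, stood at 45.8 ± 13.5 against 8.79 ± 7.63 CPM (2.14 ± 0.58) and at 67.7 ± 34.5 against 19.6 ± 9.17 CPM (1.56 ± 0.43). They rest on few reads, 221 against 32 counts for miR-449a-5p and 248 against 60 for miR-34c-3p over the 6 libraries of a group. The myeloid miR-223-3p stood at 793.8 ± 196 against 446 ± 198 CPM (0.71 ± 0.27) and miR-146a-5p at 4917 ± 2534 against 2913 ± 1140 CPM (0.57 ± 0.30). The neuronal miR-127-3p stood at 101.2 ± 37.5 against 294.5 ± 295.1 CPM (-1.64 ± 0.61). edgeR called 0 of 229 miRNAs. The smallest adjusted p of 0.124 was shared by miR-9a-5p, the paired name miR-9b-3p, miR-449a-5p and miR-34c-3p, and 11 miRNAs had an unadjusted p under 0.05 against 11.5 by chance. DESeq2 called these 4 miRNAs, and limma-voom and limma on TPM called 0, with 15, 22 and 8 at an unadjusted p under 0.05. miR-449a-5p was the 1 miRNA whose groups did not overlap.

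Whether miR-9a-5p passed in serum depended on single libraries: without saline replicate 8 or 9, edgeR called 2 names, miR-9a-5p and miR-9b-3p. Without saline replicates 10, 11 and 12 together, the log2 fold change of miR-9a-5p was 0.40, and edgeR called 2 other miRNAs, both lower after heroin: the let-7 family member miR-98-5p and the haematopoietic miR-142-3p. The panel values were 0.00 ± 0.38 for miR-128-3p, 0.16 ± 0.35 for miR-218a-5p, -0.22 ± 0.36 for let-7a-5p, -0.01 ± 0.34 for let-7c-5p, -0.49 ± 0.25 for miR-126a-3p and -0.73 ± 0.53 for miR-122-5p (4476 ± 2584 against 7074 ± 5702 CPM). For the red cell miRNAs miR-451-5p and miR-486 they were 0.15 ± 0.51 and -0.42 ± 0.32. The log2 ratio of miR-451-5p to miR-23a-3p, a measure of red cell lysis, was 3.55 ± 1.27 in heroin and 3.68 ± 0.88 in saline libraries (SD, n = 6). The difference of -0.13 was within the spread in an exact two-sided permutation test (p = 0.833).

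**Figure D2:**
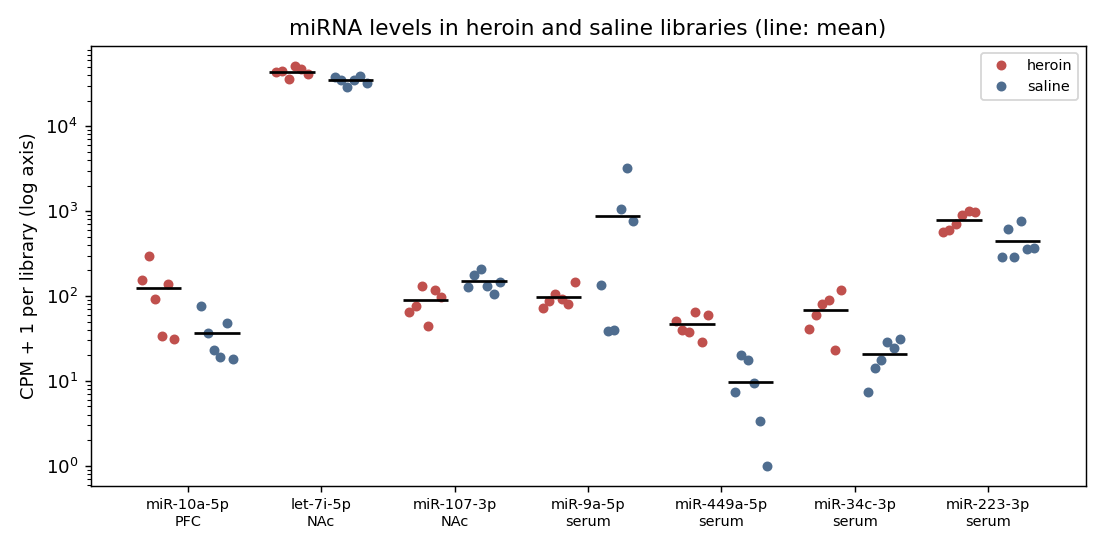
CPM + 1 of each library on a log axis for 7 miRNAs after heroin (red) and saline (blue), 6 libraries per group; the black line is the mean. None passed in edgeR; in serum, miR-9a-5p reached 3195 CPM in a saline library, and the miR-449a-5p groups did not overlap.

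As groups, 6 of the 18 lists tested in serum passed in camera with its preset correlation, and 0 did so with an estimated correlation or with fry, against 7 at an unadjusted p under 0.05. Lower after heroin was the neuron-enriched list, with 7 of 8 members negative and a median of -0.53, led by miR-9a-5p, miR-127-3p, miR-129-5p (-1.37 ± 0.80) and miR-434-3p (-0.57 ± 0.41). Its adjusted p was 0.0338 (adjusted p = 0.341 with an estimated correlation), and without saline replicates 10, 11 and 12 it no longer passed, its test pointed up, its median was 0.35, and miR-127-3p and miR-129-5p were at 0.79 and 2.35. The let-7 family had 9 of 9 members negative, among them miR-98-5p (-1.02 ± 0.51) and let-7i-5p (-0.62 ± 0.35), with a median of -0.22 and an adjusted p of 0.0484 (adjusted p = 0.613 with an estimated correlation). Higher after heroin were 4 lists. The leukocyte and microglia list had 10 of 12 members positive, such as miR-223-3p and miR-146a-5p but not miR-142-3p (-0.73 ± 0.42), with a median of 0.32. The platelet list, which shares miR-223-3p and miR-21-5p (0.30 ± 0.25) with it, had 8 of 10 positive and a median of 0.37, with miR-199a-3p at 0.57 ± 0.32. The choroid plexus and ciliated ependyma list had 3 of 5 positive and a median of 0.68, with miR-34b-3p at 0.68 ± 0.69. Its negative members were miR-204-5p (-0.23 ± 0.46) and miR-34c-5p, the other arm of miR-34c-3p. The epithelial miR-200 family had 7 of 7 positive and a median of 0.54, with miR-182 (0.68 ± 0.32), miR-141-3p (0.72 ± 0.41) and miR-200c-3p (0.58 ± 0.37). Their adjusted p was 0.031, 0.0338, 0.031 and 0.0338 in that order (adjusted p = 0.341 with an estimated correlation for the first of these lists, the platelet list and the choroid plexus list, and 0.538 for the miR-200 family).

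These list calls moved with single serum libraries. The number of lists past the threshold was 0 without heroin replicate 6 or saline replicate 11, 1 without heroin replicate 3, 2 without heroin replicate 5 and 3 without heroin replicate 4, saline replicate 9 or saline replicate 12. It was 4 without saline replicate 7 or 8, and 7 without heroin replicate 1. Other lists entered some of these counts: the miR-17 cluster without saline replicate 7 and the inflammation list without heroin replicate 1. Without saline replicate 10, the inflammation list passed and the neuron-enriched list did not. With repeated names counted once, 4 passed, and the neuron-enriched and miR-200 lists did not. Without saline replicates 10, 11 and 12 together, the let-7 list passed downward and the choroid plexus and miR-200 lists upward, while the neuron-enriched, leukocyte and platelet lists did not pass. With no low-count filter the let-7 list did not pass. Of the 12 fits that left out a library, the choroid plexus list passed in 8, the leukocyte list in 7, the platelet list in 6 and the other 3 lists in 5 each. Over all alternatives, the adjusted p ran from 0.0113 to 0.453 for the neuron-enriched list, 0.000767 to 0.836 for let-7, 0.00803 to 0.758 for leukocytes, 0.0137 to 0.341 for platelets, 0.000793 to 0.341 for the choroid plexus list and 0.000793 to 0.538 for the miR-200 family.

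The remaining serum lists did not pass with all libraries. Without saline replicates 10, 11 and 12 together, 4 of them did: the erythrocyte and miR-30 lists downward, and the inflammation list and the Dlk1-Dio3 cluster upward, the last against its negative median with all libraries. With no low-count filter, the inflammation list and the miR-17 cluster passed upward. The inflammation list also did so without heroin replicate 1 or saline replicate 10, and the miR-17 cluster without saline replicate 7. The inflammation list had a median of 0.24 (adjusted p = 0.0812) and the astrocyte list 0.25 (0.186), with miR-27a-3p at 0.49 ± 0.32, and the miR-17 cluster 0.12 (0.186). The erythrocyte list had a median of -0.32, with miR-144-3p at -0.96 ± 0.65, the Dlk1-Dio3 cluster -0.35, the liver list 0.30, the Hox-cluster list 0.05 and the miR-30 family -0.04, or 0.07 and 0.12 with upper-quartile factors and library size alone (adjusted p = 0.986 each). The activity list had a median of -0.27, the striated muscle list -0.24 and the opioid- or reward-linked list 0.00 with a mean of -0.21 and an upward test, or 0.04 and 0.11 with those scalings (0.948 each), and the vascular list -0.23 (0.455). The miR-29 family had 2 measured members and the oligodendrocyte list 1, and neither was tested. No list member passed over all miRNAs tested. Adjusted over the list alone, miR-9a-5p passed in 3 lists (neuron-enriched, activity, and opioid- or reward-linked), and miR-34c-3p and miR-449a-5p passed in the choroid plexus list. Scaling by library size alone moved the median log2 fold change of all miRNAs by -0.12 in the PFC, -0.15 in the NAc and 0.13 in serum, and none of the 6 serum lists changed direction with any scaling.

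**Figure D3:**
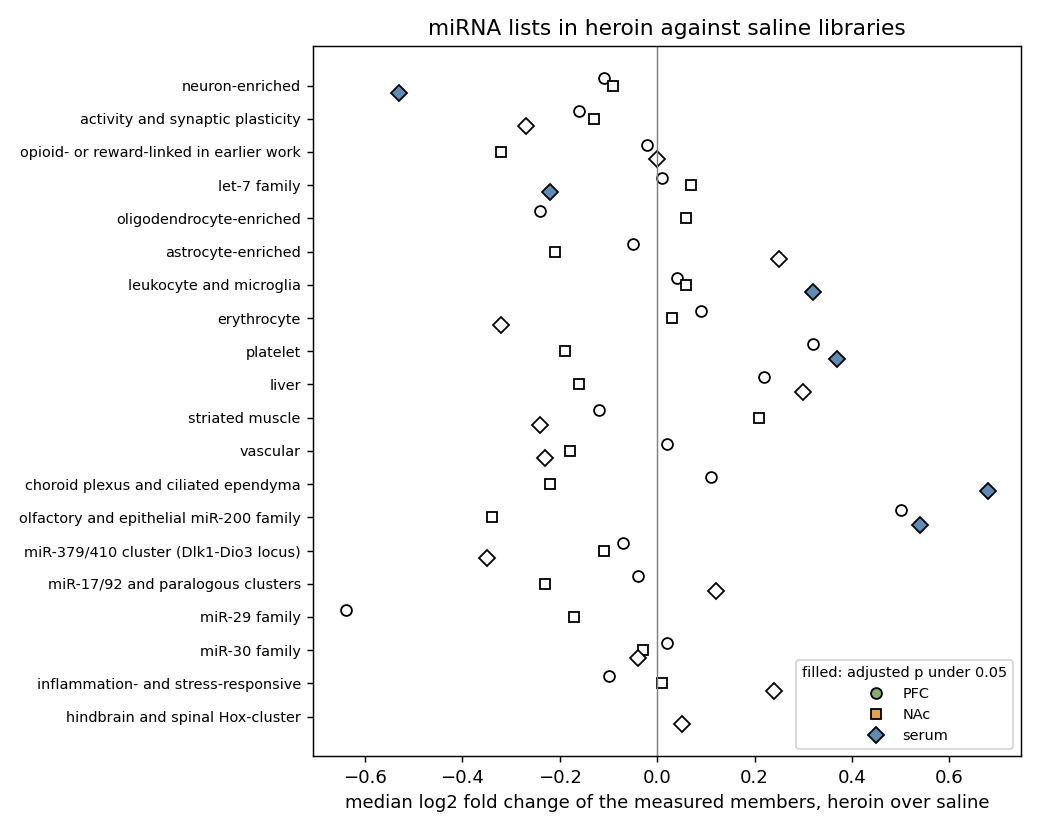
Median log2 fold change of heroin over saline for the measured members of each tested miRNA list, in the PFC (circles), NAc (squares) and serum (diamonds); filled symbols passed an adjusted p of 0.05 in camera. The 6 filled symbols are all in serum, from -0.53 for the neuron-enriched list to 0.68 for the choroid plexus list, and 0 lists passed with an estimated correlation or with fry.

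Whether the effect of heroin differed between tissues was tested for each miRNA as an interaction. Between serum and NAc, the effects of miR-329-5p, from the Dlk1-Dio3 region, differed by -3.60 ± 0.85 on the log2 scale and those of miR-34c-3p by 2.88 ± 0.70 (edgeR adjusted p = 0.0749 for both). The serum side of miR-329-5p rests on few reads, with 20 counts over the 6 saline libraries (0 to 14.06 CPM). Between serum and PFC, the effects of miR-9a-5p differed by -3.61 ± 0.95 (adjusted p = 0.157) and those of miR-10a-5p by -2.19 ± 0.68. The difference of miR-9a-5p rested on serum saline replicates 10, 11 and 12: it was 0.26 without them, and that of miR-329-5p between serum and NAc was then -2.44. Between NAc and PFC, the largest differences named were 1.38 ± 0.53 for miR-1224, 1.5 ± 0.59 for miR-664-2-5p and -1.90 ± 0.80 for miR-1912-3p. Without PFC saline replicate 8, which held 465.4 CPM of miR-1224, the first 2 were 0.77 and 0.52, and without PFC saline replicates 8 and 12 they were 0.26 and 0.32. No interaction passed in edgeR: 0 of 506 for NAc against PFC, 0 of 462 for serum against PFC and 0 of 489 for serum against NAc, with 19, 25 and 39 at an unadjusted p under 0.05. DESeq2 called 0, 2 and 1, limma-voom 0, 0 and 1, and limma on TPM 0, 0 and 0. For serum against PFC, edgeR called 2 names (miR-9a-5p and the paired miR-9b-3p) without serum saline replicate 7, 8 or 9. For serum against NAc it called 1 without serum heroin replicate 3 or serum saline replicate 7, 2 without NAc saline replicate 12 and 3 without serum saline replicate 8, serum saline replicate 9 or NAc heroin replicate 3, always with miR-329-5p among them.

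Across miRNAs, the heroin effects of the tissues were compared by correlation, with 100 relabellings of the libraries for the permutation p since miRNAs are not independent replicates. Each tissue was relabelled separately, so the permutation p does not allow for tissues that may come from the same animal. Between PFC and NAc, Pearson's r was -0.04 and Spearman's rho -0.06 over 452 miRNAs (permutation p = 0.91 and 0.86; adjusted over the 3 pairs, 0.91 and 0.86). Between PFC and serum, r was 0.05 and rho 0.13 over 209 miRNAs (permutation p = 0.84 and 0.48; adjusted 0.91 and 0.72). Between NAc and serum, r was -0.26 and rho -0.27 over 211 miRNAs (permutation p = 0.09 and 0.15; adjusted 0.27 and 0.45). The central 95% of relabelled r values ran from -0.48 to 0.44, from -0.32 to 0.30 and from -0.23 to 0.37 for the 3 pairs. The value for NAc and serum lay just below its range, while 9 of 100 values were as large in size. The NAc and serum value was -0.31 without serum heroin replicate 1 and -0.34 without replicate 2 (unadjusted permutation p = 0.04 and 0.03, from draws that gave 0.13 with all libraries), and -0.06 without serum saline replicate 12.

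As background to the heroin effects, the NAc and the PFC of saline rats were compared. Higher in the NAc was miR-187-3p, at 170.9 ± 57.4 against 18.3 ± 13.4 CPM (log2 fold change 3.24 ± 0.44 SE, n = 6 per group). So were miR-1298, at 1550 ± 442 against 224.5 ± 108.4 CPM (2.66 ± 0.39), and miR-7a-5p, at 84060 ± 35750 against 14840 ± 5589 CPM (2.36 ± 0.40). Lower in the NAc were miR-128-3p, at 29790 ± 8803 against 92580 ± 74930 CPM (-1.75 ± 0.39), miR-132-5p (-1.32 ± 0.30) and miR-146b-5p, at 1079 ± 97.7 against 2415 ± 339 CPM (-1.27 ± 0.20). PFC saline replicate 12 held 245000 CPM of miR-128-3p against 53440 to 71790 in the others, and without it the log2 fold change was -1.21 and still passed. Of 467 miRNAs, 33 passed in edgeR, 17 higher and 16 lower in the NAc, and 113 had an unadjusted p under 0.05; for 32 miRNAs the groups did not overlap, which chance gives for 0.216% of miRNAs. Further named miRNAs past the threshold were miR-10a-5p (1.96 ± 0.38), miR-7b (1.96 ± 0.37), miR-369-3p, miR-344a-3p and miR-487b-3p among the higher, and miR-24-2-5p (-1.81 ± 0.34), miR-1224, miR-582-3p and miR-1843b-5p among the lower. Of these, miR-369-3p, miR-1843b-5p, miR-487b-3p and miR-1224 lost their calls in 9, 9, 8 and 6 of the 12 fits that left out a library, and miR-1224 moved from -1.67 to -1.14 without PFC saline replicate 8.

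By list, the choroid plexus and ciliated ependyma list had 4 of 10 members higher in the NAc and none lower: miR-1298, and miR-448-3p (60.3 against 6.4 CPM, 3.04 ± 0.37), miR-448-5p (2.91 ± 0.65) and miR-1912-3p (3.62 ± 0.64), which, like miR-1298, are encoded in Htr2c. The striated muscle list had 2 of 5 lower, miR-1-3p (-2.11 ± 0.24) and miR-206-3p (-1.83 ± 0.46), and the opioid- or reward-linked list 3 of 21 lower, with miR-592 (-1.38 ± 0.37). In the PFC, miR-206-3p was at 164.3 CPM in saline replicate 8 and 15.74 to 76.74 in the others. Without that library its value was -1.39, and it no longer passed without NAc saline replicate 10 or 11. The call of miR-592 was lost in 10 of the 12 fits that left out a library. The activity list had 2 higher and 1 lower of 17, the neuron-enriched list 1 higher and 1 lower of 20, and the Dlk1-Dio3 cluster 2 higher of 28. The vascular and Hox-cluster lists each had miR-10a-5p higher (of 11 and 2 members), and the leukocyte and inflammation lists each had miR-146b-5p lower (of 11). No member passed in the let-7 (9), oligodendrocyte (6), astrocyte (9), erythrocyte (10), platelet (9), liver (6), miR-200 (5), miR-17 cluster (9), miR-29 (6) and miR-30 (8) lists. The number of calls was 58 with DESeq2, 71 with limma-voom and 52 without PFC saline replicate 12, and upper-quartile scaling, which moved the median by 0.12, called 21 higher and 12 lower. With scaling by library size alone, 17 were higher and 9 lower.

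**Figure D4:**
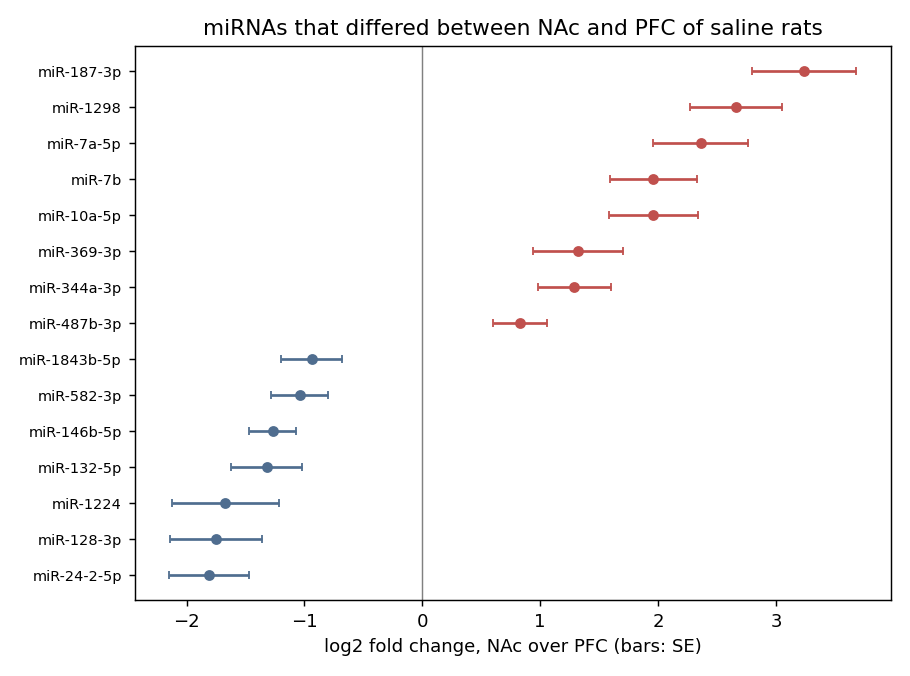
Log2 fold change of NAc over PFC in saline rats, with its SE as a bar, for the named miRNAs that passed the threshold; values above 0 (red) are higher in the NAc. They run from -1.81 for miR-24-2-5p to 3.24 for miR-187-3p.

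Serum of saline rats held several miRNAs of blood cells and muscle, and the liver miRNA miR-122-5p, at far higher levels than brain, and several miRNAs of neurons at far lower levels. miR-451-5p, made in red cell precursors, stood at 26720 ± 14890 CPM in serum against 28.0 ± 14.7 in the PFC (log2 fold change 9.68 ± 0.74 SE, n = 6 per group) and 28.4 ± 12.3 in the NAc (9.52 ± 0.63). The muscle miRNA miR-1-3p stood at 37480 ± 20950 CPM in serum against 55.1 ± 14.2 (9.31 ± 0.67) and 13.5 ± 2.93 (11.14 ± 0.62), and against the NAc the log2 fold changes of miR-133a-3p and miR-206-3p were 9.50 ± 0.61 and 9.46 ± 0.68. The liver miRNA miR-122-5p stood at 7074 ± 5702 CPM against 2.61 ± 3.31 in the PFC (11.48 ± 0.90) and 24.4 ± 38.4 in the NAc (7.78 ± 1.42). NAc saline replicates 7 and 9 held 92 and 49.8 CPM of it, and without both the NAc level was 1.09 ± 0.337 CPM (n = 4) and the log2 fold change 12.05 ± 1.14. The myeloid miR-223-3p stood at 446 ± 198 CPM against 0.834 ± 0.718 (8.91 ± 0.72). Without serum saline replicate 12, the log2 fold changes of miR-1-3p and miR-122-5p against the PFC were 8.46 and 10.53. On the other side, miR-9a-5p stood at 873.4 ± 1215 CPM in serum against 158100 ± 47440 in the PFC (-7.83 ± 1.04) and miR-212-5p at 8.63 ± 15.5 against 1877 ± 1104 (-8.04 ± 0.88). miR-329-5p stood at 6.75 ± 5.23 against 1406 ± 837 (-7.86 ± 0.81), and miR-7b had a log2 fold change of -8.31 ± 1.04 against the NAc. The mean serum level of miR-9a-5p came mostly from saline replicates 10, 11 and 12, at 1068, 3195 and 765.7 CPM. Without replicate 11 the log2 fold changes were -8.99 for miR-9a-5p and -9.95 for miR-212-5p against the PFC and -10.54 for miR-7b against the NAc. Without all 3 libraries they were -12.33, -11.60 and -12.59, that of miR-329-5p was -9.71, and those of miR-1-3p and miR-122-5p were 7.84 and 9.58 against the PFC. The PFC levels of miR-582-3p, miR-325-5p and miR-329-3p were 499.5, 236.9 and 241.6 CPM, and each had 2 counts in all 6 serum libraries together. In edgeR, 348 of 407 miRNAs passed between serum and PFC (137 higher and 211 lower in serum) and 384 of 424 between serum and NAc (143 higher and 241 lower). At an unadjusted p under 0.05 there were 351 and 385, and the groups of 274 and 308 did not overlap.

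By list, all measured members were higher in serum than in each brain region in the erythrocyte (10), striated muscle (7), miR-200 (8) and Hox-cluster (4) lists. All 19 members of the neuron-enriched list were lower, such as miR-124-3p (-7.41 ± 0.74) and miR-434-3p (-6.28 ± 0.48 against the PFC), as were 16 of 17 activity miRNAs such as miR-132-3p (-6.81 ± 0.61). In the Dlk1-Dio3 cluster 24 of 25 were lower than in the PFC and 27 of 27 than in the NAc. Against the PFC, higher and lower members numbered 9 and 0 of 11 for leukocytes, 8 and 0 of 10 for platelets, 5 and 1 of 6 for liver and 9 and 1 of 10 for the miR-17 cluster. In the liver list, miR-194-5p, miR-192-5p and miR-148a-3p had log2 fold changes of 1.92 ± 0.44, 1.61 ± 0.47 and 1.90 ± 0.58 against the PFC, far below that of miR-122-5p, and miR-365-3p was lower than in the NAc (-1.97 ± 0.52). Higher and lower members numbered 1 and 5 of 6 for oligodendrocytes, 1 and 6 of 8 for miR-30 and 0 and 3 of 4 for miR-29. The opioid- or reward-linked list had 6 and 14 of 21, and the choroid plexus list 2 and 3 of 6. Lists whose median turned with the scaling against the PFC were let-7, with 4 higher and 1 lower of 9 (median 0.73, and 0.00 with RLE size factors), inflammation, with 5 and 5 of 11 (0.22 and -0.49), and vascular, with 2 and 2 of 10 (-0.74, and 0.18 with upper-quartile factors). Against the NAc, let-7 had 5 higher and 2 lower (0.63, and -0.05 with RLE size factors), vascular 3 and 2 (-0.55, and 0.54 with upper-quartile factors) and the astrocyte list 3 and 5 of 9 (-0.86 and 0.23). The median of all miRNAs was -1.45 against the PFC and -1.91 against the NAc. RLE size factors moved these by -0.80 and -0.63, and upper-quartile factors by 0.91 and 1.08, so a difference of that size in serum against brain depends on the scaling.

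**Figure D5:**
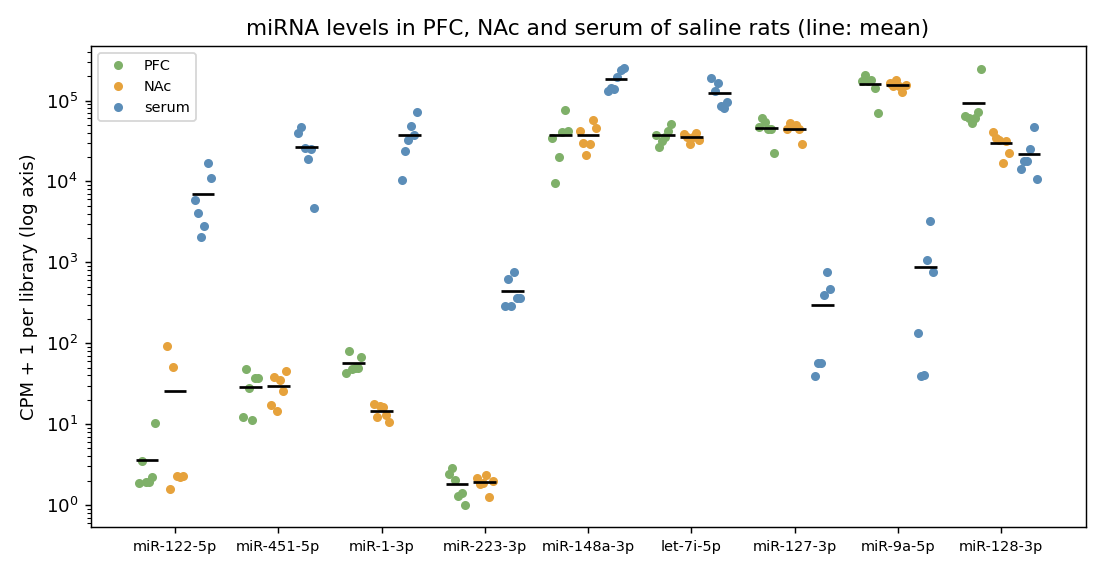
CPM + 1 of each saline library on a log axis for 9 miRNAs in the PFC (green), NAc (orange) and serum (blue), 6 libraries each; the black line is the mean. Mean levels in serum and PFC were 26720 and 28.0 CPM for miR-451-5p, and 873.4 and 158100 CPM for miR-9a-5p.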

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

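The counts over other splits of the libraries were planned before their results were seen. The tests on the 3 patterns of single libraries were chosen only after those patterns were seen. For PFC saline replicates 8 and 12, the bound of the arm test was moved from 0.5 to the lower bound of the difference between NAc and PFC, and the label test was split by library, with a different test for replicate 12, after their values were seen.

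Other splits of the libraries into groups of the same sizes were counted, 100 for each result with the real one included. Where the real count is 0, every split reaches it (100 of 100), so the number decides nothing; this holds for heroin against saline in each tissue, for the lists in the PFC and NAc, and for the interactions. For heroin against saline, the highest of the other splits called 47 miRNAs in the PFC, 48 in the NAc and 5 in serum, and 2, 6 and 4 of the 99 others called any. A split with 47 or 48 calls points to a structure of the libraries, which was not tested. For the lists, the highest others were 4 in the PFC and 7 in the NAc, and 51, 59 and 76 of the 99 others called at least 1 list in the PFC, NAc and serum, so a call of camera with its preset correlation was common under other splits. In serum, 11 of 100 splits reached the real 6 (highest other 7), so chance cannot be excluded for the serum lists. For the interactions, the highest others were 6 for NAc against PFC, 18 for serum against PFC and 8 for serum against NAc, and 6, 14 and 24 of the 99 others called any. For the tissues of saline rats, 1 of 100 splits, the real one, reached 33, 348 and 384 calls, the highest other being 0 each. Such numbers were thus rare under other splits, but 100 splits cannot show a share below 1 in 100. Splits that mix the tissues also widen the spread within groups, which makes calls in them less likely. For the correlations of heroin effects, 91, 84 and 9 of 100 relabellings gave an r as large in size as the real -0.04, 0.05 and -0.26 for PFC and NAc, PFC and serum, and NAc and serum (highest others -0.54, -0.42 and 0.42), so chance cannot be excluded.

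Among 333 groups of 6 values (levels of named miRNAs, totals and similarity of libraries), 38 held a library far from the other 5 by a test that chance meets in about 1 in 20 groups. PFC saline replicate 12 did so most often. It held 245000 CPM of miR-128-3p (others 53440 to 71790), 27300 of let-7c-5p (8961 to 11750), 2804 of miR-485-3p (103.6 to 146.1), 167.9 of miR-338-3p (33.65 to 53.77), 9.24 of miR-122-5p (0.89 to 2.473) and 7.987 of miR-122b (0.712 to 1.237). It was low in miR-9a-5p at 70710 CPM (142700 to 206600), the paired miR-9b-3p at 70510 (142100 to 206100), miR-127-3p at 22580 (44550 to 61180), miR-329-5p at 82.85 (1208 to 2623), and the share of repeated names at 13.32% (22.65% to 26.52%). PFC saline replicate 8 held 8818 CPM of let-7f-5p (31420 to 64740), 2144 of miR-138-5p (102.7 to 195.3), 341.2 of miR-29c-3p (10.9 to 35.55) and 226.9 of miR-331-3p (5.65 to 11.12).

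Serum saline replicate 12 had a mean correlation of 0.819 with the other serum libraries (0.908 to 0.937 for the others of its group) and an SD of 1.64 from the median library (0.50 to 0.89). It held 20320 CPM of let-7g-5p (47600 to 63020), 7318 of miR-26a-5p (47120 to 85950) and 78.06 of miR-182 (200.6 to 309.2). Serum heroin replicate 1 had 2.778 M counts (M, 1e+06; 0.162 to 0.615). PFC heroin replicate 2 held 86.86 CPM of miR-122-5p (0.662 to 4.509), 75.74 of miR-122b (0.4875 to 3.544) and 317.6 of miR-138-5p (114.7 to 167.9). NAc heroin replicate 2 held 97.04 CPM of miR-122-5p (0.68 to 2.989), 42620 of let-7f-5p (55800 to 60380), 41340 of the paired miR-3596d (54010 to 58160) and 25340 of miR-7a-5p (73480 to 115300). NAc heroin replicate 3 held 9422 CPM of let-7a-5p (4871 to 6206) and 4.798 of miR-34c-3p (0.813 to 1.221). NAc saline replicate 7 held 4847 CPM of miR-126a-3p (3216 to 3741), 43.94 of miR-24-2-5p (24.48 to 29.44), 2267 of miR-708-3p (1037 to 1363) and 331.3 of miR-99b-3p (215.4 to 243.7). NAc saline replicate 12 held 28880 CPM of miR-127-3p (44350 to 52700), 266.1 of miR-153-3p (157 to 188) and 466.8 of miR-329-3p (191.6 to 257.6), and NAc saline replicate 10 held 49.83 of miR-344b-1-3p (117.3 to 151).

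PFC saline replicates 8 and 12 lay 1.31 and 1.26 (SD of log2 differences) from the median PFC library, and lower depth is argued against by the 2 PFC libraries of fewer reads, which lay at most 0.43 from it. On an axis from 0 at the PFC to 1 at the NAc, replicate 8 lay at -0.12, within the range of the other PFC libraries (-0.36 to 0.30). This argues against a NAc library under a PFC label, but the axis cannot show tissue of another region. Replicate 12 lay at 0.53 (lowest NAc saline library 0.81), but NAc tissue as its whole cause, by label or mixture, is argued against by 21 of 161 miRNAs over 2-fold outside the range of the other brain libraries, against at most 2 in any of those 22, such as miR-128-3p at 245000 CPM (16680 to 46100 in the NAc); NAc tissue as a part of it stays open. A different cell makeup of the dissected tissue stays open, since the arms of 60 precursors deviated together with r = 0.19 (-0.06 to 0.43) in replicate 8 and 0.28 (0.02 to 0.50) in replicate 12, overlapping at its upper end the 0.60 (0.42 to 0.73) of the real difference between NAc and PFC. No biological explanation from the design was tested, as both libraries are from saline rats like 4 others.

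Serum saline replicates 10, 11 and 12 held 1068, 3195 and 765.7 CPM of miR-9a-5p against 38.1 to 146.4 in the other serum libraries. Lower depth is argued against by the 6 other serum libraries with as few or fewer reads, in which miR-9a-5p reached at most 133.4 CPM. Brain RNA in those libraries is a candidate explanation: miR-127-3p, miR-129-5p, miR-379-5p and miR-7b, abundant in brain, rose by a median of 0.85, 0.86 and 1.71 times the rise that the miR-9a-5p level predicts, although miR-7b alone rose by 0.10, 1.58 and 0.30 times. The share of brain RNA this would need is 0.634%, 2.02% and 0.437%. Whether it came from handling or from a difference between the rats was not tested, and treatment cannot account for it alone, since saline replicates 7, 8 and 9 did not show it.

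PFC heroin replicate 2, NAc heroin replicate 2 and NAc saline replicates 7 and 9 held 86.86, 97.04, 92 and 49.8 CPM of miR-122-5p and 46.8, 24.3, 25.02 and 23.4 CPM of miR-200a-3p, against at most 9.24 and 18.0 in the other PFC libraries and 2.99 and 5.47 in the other NAc libraries. Serum RNA in these libraries is argued against, since miR-1-3p, miR-206-3p, miR-451-5p and miR-486 rose by a median of at most 0.01 times the rise predicted from miR-122-5p, with miR-451-5p at 26.6, 22.1, 16.3 and 13.6 CPM where 447.5, 512.6, 487.5 and 276.7 were predicted. Lower depth stays open. The 3 other brain libraries with as few reads as NAc saline replicate 9 were all from the PFC. In them, miR-122-5p reached at most 9.24 CPM. In the NAc, the high libraries had the fewest counts (5.895, 6.076 and 7.813 M, against at least 11.77 M in the others). PFC heroin replicate 2 also had the fewest counts of the PFC libraries (3.419 M). No biological explanation was tested, as the libraries come from both treatments and both brain regions, and RNA of another tissue rich in both miRNAs was not tested.

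The pair miR-34c-3p and miR-449a-5p in heroin serum was tested first and then left out of the weighing in favour of miR-122-5p. Of 12 serum libraries, 7 had under 10 counts of a member (2 heroin and 5 saline). The 10 measured of 13 epithelial miRNAs had a median log2 fold change of 0.30 (highest 0.72) against 1.85 for the pair. Of the miRNAs made from the same transcript as miR-34c-3p, miR-34b-3p was at 0.68 ± 0.69 and miR-34c-5p at -0.21 ± 0.66.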

How the results depend on the processing

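Chosen only after the data were seen were the settings that left out named libraries together and the one that counted repeated names once; the latter moved no count by over 1.5 times, but left 4 of the 6 serum lists past the threshold, without the neuron-enriched and miR-200 lists. For heroin against saline, 0 miRNAs passed in the PFC and NAc under every alternative. In serum, 4 passed with DESeq2 (miR-34c-3p, miR-449a-5p, miR-9a-5p and the paired miR-9b-3p), 2 with no low-count filter (miR-9a-5p and miR-9b-3p), 4 with all 36 libraries in one fit (those, miR-127-3p and miR-329-5p), and 2 without saline replicates 10, 11 and 12 (miR-142-3p and miR-98-5p). In that last setting the neuron-enriched list turned upward (adjusted p = 0.4137, in a range of 0.0113 to 0.453 over its alternatives). The leukocyte and platelet lists no longer passed, the let-7, choroid plexus and miR-200 lists did, and 4 others passed: the erythrocyte and miR-30 lists downward, the inflammation list and the Dlk1-Dio3 cluster upward. Of the lists in serum, 6 passed, 0 with an estimated correlation, 0 with fry and 3 with the libraries that stand apart left out (let-7, choroid plexus and miR-200); in the PFC, 2 passed with no low-count filter (platelet and Hox-cluster) against 0. For the interactions, DESeq2 called 2 for serum against PFC. For serum against NAc, 1 passed with upper-quartile factors, 1 with DESeq2, 1 with limma-voom and 5 with the stricter filter. For NAc against PFC in saline rats, 33 calls became 58 with DESeq2, 71 with limma-voom and 56 with the libraries that stand apart left out. The correlation between NAc and serum was -0.06 with the libraries that stand apart left out and 0.06 without serum saline replicates 10, 11 and 12, against -0.26. The cause was not tested.

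Leaving out 1 library at a time gave 0 to 2 calls in serum (2 without saline replicate 8 or 9), 0 to 4 lists in the PFC (4 without heroin replicate 5) and 0 to 3 in the NAc (3 without heroin replicate 2). It gave 0 to 7 lists in serum (0 without heroin replicate 6 or saline replicate 11). For the interactions it gave 0 to 2 for serum against PFC and 0 to 3 for serum against NAc, and for NAc against PFC in saline rats 25 to 52 (52 without PFC saline replicate 12). The correlation between NAc and serum ran from -0.34 to -0.06, that between PFC and NAc from -0.20 to 0.19, and the red cell difference from -0.50 to 0.26. Serum against PFC gave 303 to 386 calls and serum against NAc 331 to 417. Of values of named miRNAs that had not passed, 32 of 588 changed sign over the alternatives in the PFC, 33 of 595 in the NAc and 33 of 529 in serum. Calls were lost in 53 of 373 values for NAc against PFC, and in 1 of 496 and 1 of 516 for serum against PFC and NAc.

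With the replicate number as a block, 0 interactions passed for each pair of tissues, and 30, 348 and 372 miRNAs passed for NAc against PFC, serum against PFC and serum against NAc. Over 200 miRNAs, libraries of the same number correlated above 0.1 in 7 of 12 numbers between PFC and NAc, 7 of 12 between PFC and serum and 6 of 12 between NAc and serum. Among 6 candidates each, 6, 6 and 3 of 12 correlated best with their own number. Between PFC and NAc, the mean r of same and different numbers was 0.42 and -0.09 in heroin rats and 0.13 and -0.02 in saline rats. For PFC and serum it was 0.03 and -0.01, and 0.17 and -0.03. For NAc and serum it was 0.07 and -0.01, and 0.10 and -0.02. This is a hint of pairing from the data and not the design. The numbers were not taken to pair the samples, so the fits without a block and the relabellings for the correlations may treat tissues of the same animal as independent.

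Depth and spread limit what was detectable. In simulated counts, 2-fold changes were recovered for 43.3% of miRNAs in the PFC, 72.5% in the NAc and 43.1% in serum. They were recovered for 6.6% and 4.4% in the interactions of serum with PFC and NAc. In the PFC, NAc and serum simulations, 255 of 455, 280 of 480 and 29 of 229 miRNAs were left unchanged. So many changes make the adjusted threshold easier to pass than a few changes would. The rates can thus overstate the power to detect a few changes. The stricter filter tested 285 miRNAs in serum heroin vs saline against 229 otherwise, so it is not stricter there.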
